A study of Mus musculus with 4 samples.

How the data were processed

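Lungs of WT and LAIR1KO mice, normal or bearing B16/F10 melanoma, were dissociated and profiled as single cells with a 10x Genomics 3' kit, version 3, per the labels' protocols. The series design names 3 hashtagged replicates in each of the 4 groups, and each group has a single library of gene expression together with antibody capture, per the labels. For each library the authors deposited a matrix of counts (unique molecular identifiers, UMIs, per feature and barcode) with its features and barcodes. Reads were turned into these counts with Cell Ranger 4.0.0 and STAR on mm10, per the submitters' processing notes, which also list R 4.0.0 and Seurat 3.2.0 and give no version for STAR. The deposited counts are whole numbers with no normalization, for 32285 genes and for the hashtag antibodies, and the barcodes are those left after the calling of cells, per the file contents. An annotation of the cells by others was not used here.

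Cells were kept with at least 300 detected genes and at most 10% mitochondrial UMIs, which left 15793 of 16350 barcodes. Hashtag counts were assigned to animals per library with HTODemux of Seurat 5.3.0 (R 4.3.3, positive quantile 0.99). Doublets of 2 hashtags (18.42, 13.87, 22.06 and 14.96% of filtered cells in WT normal, WT tumor-bearing, LAIR1KO normal and LAIR1KO tumor-bearing) and cells with no hashtag (23.71, 33.95, 25.60 and 32.03%) were set aside, leaving 8461 cells in 12 replicates. Scrublet marked 286 cells (1.81%), 114 among those kept, which stayed in except in one alternative. Cells of all libraries were scaled to 10000 UMIs, log-transformed and clustered with scanpy 1.11.5 and leidenalg 0.10.2 on Python 3.11.15 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1.0), without integration across libraries, into 31 clusters. Clusters were named from marker lists, and a name ending in "-like" rests on those markers alone. Clusters led by genes of several classes stayed unnamed. Monocytes were parted into classical and non-classical by sub-clustering of one cluster (500 variable genes, 10 components, resolution 0.5). Differences from other descriptions of these lungs may come from these rebuilt names.

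The replicate was the animal, not the cell. UMIs were summed per replicate and class, with at least 10 cells, and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr), with all groups sharing the estimate of spread. Benjamini-Hochberg adjusted p under 0.05 passed. CPM are UMIs of a gene scaled to a common total per replicate. The contrasts were genotype in normal and in tumor-bearing lung, tumor in WT and in LAIR1KO, and the interaction. Shares of cells were tested with the edgeR quasi-likelihood test on cell numbers with the total as offset, and with an exact permutation test, two-sided, whose smallest p is 0.1. For the classes of the title, the text names in each contrast the 4 risen and 4 fallen genes with the smallest p among those past the threshold, changed at least 1.5-fold, with a mean of at least 20 CPM in the higher group and all 3 replicates of one group above those of the other (chance gives 10% of genes such a separation). In other classes it names 2 and 2. Sex-linked, immunoglobulin and T cell receptor variable, ribosomal and mitochondrial genes and gene models were passed over. Lair1 was always included, and up to 4 members were added of a fixed list with at least 2 members past the threshold. Where the planned test lacked cells, the 10 genes with the largest log2 ratio among those with at least 50 UMIs in the higher group were taken, and the text gives part of them. These rules, the gene lists, the markers, the tests and the first set of alternatives were chosen before the data were examined.

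Altogether 30 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry. The text reports the lists with members past the threshold or a call in the classes it describes. Median log2 fold changes of lists are of fitted values. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. Intervals of counts are exact at 95%, and intervals and floors cover counting error only. Of 32285 genes 32158 were matched to a position.

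The gene test was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For genotype in tumor-bearing lung it recovered 67% of genes changed 2-fold and 94% of those changed 4-fold in interstitial macrophage-like cells (7534 genes in that step, 11 unchanged genes called), and 70% and 91% in neutrophil-like cells (3326 genes, 7 called). The number of cells per replicate sets what could be seen. LAIR1KO normal replicate 1 held 14 interstitial macrophage-like cells, against 179 once cells without a hashtag call were rescued. Classical and non-classical monocyte-like cells were below the minimum of 10 per replicate, except for 15 classical ones in LAIR1KO tumor-bearing replicate 3, so that the planned gene test of them could not be run.

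The first set of other settings was RLE size factors, DESeq2 1.42.0, no filter on low counts, counts thinned to the smallest replicate, fits of the 2 compared groups alone, and each replicate left out in turn. It also held a strict cell filter (500 genes, 5% mitochondrial UMIs), another rule for hashtags (a margin of 1 in natural log units), removal of Scrublet doublets, and clustering at resolutions 0.5 and 2.0. For shares they were mononuclear phagocytes as the denominator and TMM factors over the classes. Chosen after seeing the data were cells without a hashtag call rescued when the top hashtag had at least 10 counts and stood 1 natural log unit above the next, cluster 17 left out of alveolar type 2 epithelium-like cells, and genes on chromosomes X and Y left out. Also chosen then were interstitial macrophage-like cells with 5 or more UMIs of the endothelial list left out, a monocyte test with no minimum of cells, and the alveolar macrophage test within tumor-bearing lung. No median over all genes moved by more than 0.05 log2 units between scalings. Computations also used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.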

Results

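RNA of single lung cells was measured in 4 groups of mice: wild-type (WT) and LAIR1KO animals, each with normal lungs and with lungs bearing B16/F10, a mouse melanoma line. Each group was one droplet library of 3 animals marked with hashtag antibodies. Thus 12 hashtag replicates were compared, and library and group could not be told apart. The libraries held 25216301 gene UMIs in 3295 barcodes (WT normal), 27249807 in 4442 (WT tumor-bearing), 28034709 in 3886 (LAIR1KO normal) and 25877517 in 4727 (LAIR1KO tumor-bearing). After filters on cells and assignment to an animal, 1794, 2239, 1997 and 2431 cells were kept in that order, with a median of 5597, 5051, 5709 and 4293 UMIs per cell. Replicates held 577 to 1027 cells and 2645820 to 6074352 UMIs. The WT normal animals were male by their transcripts (Ddx3y, a Y-linked helicase, 181 to 207 CPM, UMIs scaled to the same total). The other 3 groups were female (Xist, the RNA that silences an X chromosome, 1116 to 1379 CPM). Only the comparison of genotypes in tumor-bearing lung and that of tumor-bearing with normal LAIR1KO lung were therefore matched for sex.

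The targeted gene was examined first, because it checks the genotype labels. Lair1 (ENSMUSG00000055541; mm10, chromosome 7, 4003402 to 4063204, minus strand) encodes an inhibitory receptor that binds collagen. In interstitial macrophage-like cells of WT mice it stood at 126 ± 9.95 CPM in normal and 188 ± 30.6 CPM in tumor-bearing lung (mean ± SD, n = 3), a difference that did not pass the test (log2 0.58 ± 0.16 SE, adjusted p = 0.154). LAIR1KO interstitial macrophage-like cells held 0 Lair1 UMIs in 210 cells of normal lung and 1 in 579 cells of tumor-bearing lung. The level in LAIR1KO normal lung was thus at least 56.6-fold lower than in WT, taking a floor of 3 counts over the group. In tumor-bearing lung it was lower by a ratio of 633 (95% counting interval 113 to 25050). Alveolar macrophage-like cells of tumor-bearing lung held 52 Lair1 UMIs in WT and 0 in LAIR1KO (at least 19-fold lower). Non-classical monocyte-like cells held 30 and 0 (at least 7.67-fold lower), and neutrophil-like cells 25 and 0 (at least 9.87-fold lower). Classical monocyte-like cells held 1 Lair1 UMI in each WT library, too few for a level but enough for an upper bound. In WT tumor-bearing lung the 95% counting interval was 0.467 to 103 CPM over the group's summed UMIs. It lay below that of non-classical monocyte-like (216 to 456) and interstitial macrophage-like cells (169 to 198). In WT normal lung it was 0.389 to 85.6, below interstitial macrophage-like (108 to 138) but overlapping non-classical monocyte-like cells (62.4 to 370). These intervals cover counting error only. A Lair1 UMI was seen in 53.3% of WT normal interstitial macrophage-like cells (median 6780 UMIs) and in 0 of 192 endothelial cell-like cells of the same library (median 5473 UMIs), a type not known for this receptor. The adjusted p for interstitial macrophage-like cells was 2.46e-07 in normal lung and 8.86e-10 in tumor-bearing lung (edgeR), and both calls held under each alternative tried.

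**Figure D1:**
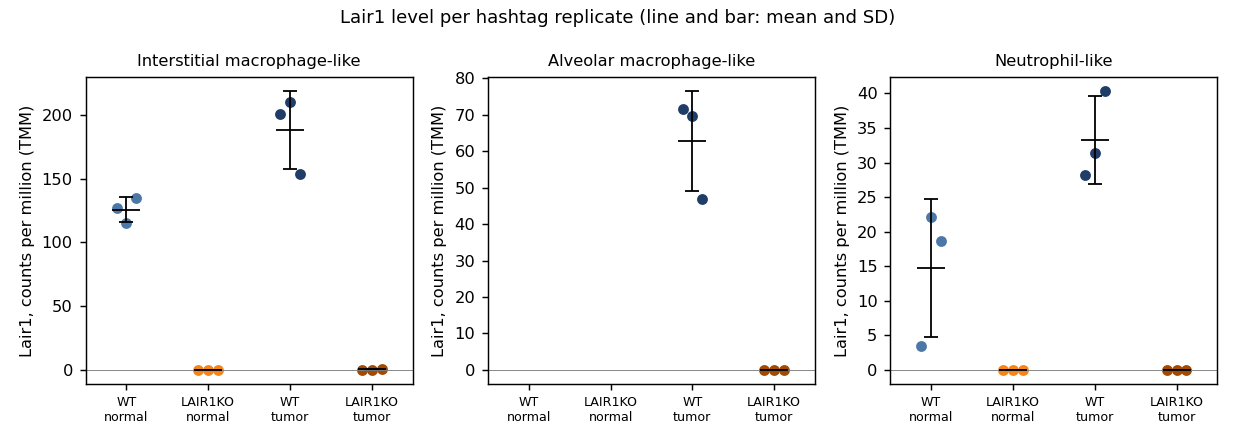
Lair1 in CPM for each hashtag replicate (points) with group means and SD (bars and lines) in interstitial macrophage-like, alveolar macrophage-like and neutrophil-like cells. Interstitial macrophage-like cells averaged 126 and 188 CPM in the WT groups, against 0 and 1 UMIs in all cells of the LAIR1KO groups.

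Cell types were compared as shares of the kept cells, since the study asks how monocytes and interstitial macrophages depend on the receptor. Monocytes were scarce in every library: non-classical monocyte-like cells, the type that patrols vessel walls, made up 0.392% ± 0.197 (SD, n = 3) of WT normal, 1.19% ± 0.281 of WT tumor-bearing, 0.205% ± 0.245 of LAIR1KO normal and 0.544% ± 0.175 of LAIR1KO tumor-bearing cells. Classical monocyte-like cells, recruited from blood, made up 0.612% ± 0.250, 0.488% ± 0.0913, 0.252% ± 0.240 and 0.867% ± 0.649 in that order. Interstitial macrophage-like cells made up 15.3% ± 5.25 of WT and 10.5% ± 7.34 of LAIR1KO normal lung cells, and 22.3% ± 6.91 and 22.7% ± 6.10 in tumor-bearing lung. None of these shares passed the edgeR test for genotype. For non-classical monocyte-like cells the log2 difference was −0.90 in normal lung (adjusted p = 0.438) and −1.04 ± 0.65 SE in tumor-bearing lung (adjusted p = 0.675). For interstitial macrophage-like cells it was −0.54 ± 0.52 (adjusted p = 0.438) and 0.03 (adjusted p = 0.960). Without LAIR1KO normal replicate 1 or 3 the values in normal lung were −0.37 or −2.18 for non-classical monocyte-like and −0.06 or −0.99 for interstitial macrophage-like cells. Hashtag loss was uneven: 56.6% of interstitial macrophage-like cells had no hashtag call in LAIR1KO normal lung, against 21.9% in WT normal lung. Over all filtered cells but hashtag doublets their share was 17.6% in LAIR1KO and 14.5% in WT normal lung, the opposite direction. In the cluster that held the monocytes, many cells were set aside as hashtag doublets. These were 57.5% in WT normal, 43% in WT tumor-bearing, 35.4% in LAIR1KO normal and 39.6% in LAIR1KO tumor-bearing lung. The low shares of monocytes and their differences depend on this loss. Tumor-bearing lung held 1.55 ± 0.72 log2 units more non-classical monocyte-like cells in WT (adjusted p = 0.213) and 1.81 log2 units more classical monocyte-like cells in LAIR1KO (adjusted p = 0.0591), neither past the threshold. The exact permutation test of 3 against 3 replicates cannot give a p below 0.1, the two-sided value it gave for non-classical monocyte-like cells between the tumor-bearing groups.

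Alveolar macrophage-like cells, the resident phagocytes of the air spaces, showed the largest tumor difference in either genotype among the classes tested. They rose from 0.111% ± 0.0964 to 4.35% ± 0.926 of cells in WT (2 against 97 cells; log2 5.08 ± 0.78, adjusted p = 7.91e-07). In LAIR1KO they rose from 0.398% ± 0.230 to 4.58% ± 0.959 (8 against 109 cells; log2 3.46 ± 0.63, adjusted p = 3.05e-05). This LAIR1KO rise of alveolar macrophage-like cells was smaller and lost its call with mononuclear phagocytes as the denominator. Natural killer cell-like cells rose in tumor-bearing LAIR1KO lung from 0.257% ± 0.191 to 2.12% ± 0.851 (log2 3.01, adjusted p = 6.57e-04, or 2.50 once cells without a hashtag call were rescued). Fibroblast-like cells were lower in LAIR1KO than in WT normal lung, at 5.67% ± 3.28 against 18.3% ± 3.02 (log2 −1.68, adjusted p = 0.0103, or 0.0528 without WT normal replicate 3). Cells of unnamed clusters were higher there, at 18.3% ± 3.83 against 3.84% ± 0.955 (log2 2.25, adjusted p = 8.23e-04). Shares depend on how each suspension was made and on the depth of each library. They also depend on hashtag calls, which were lost unevenly across classes and libraries.

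**Figure D2:**
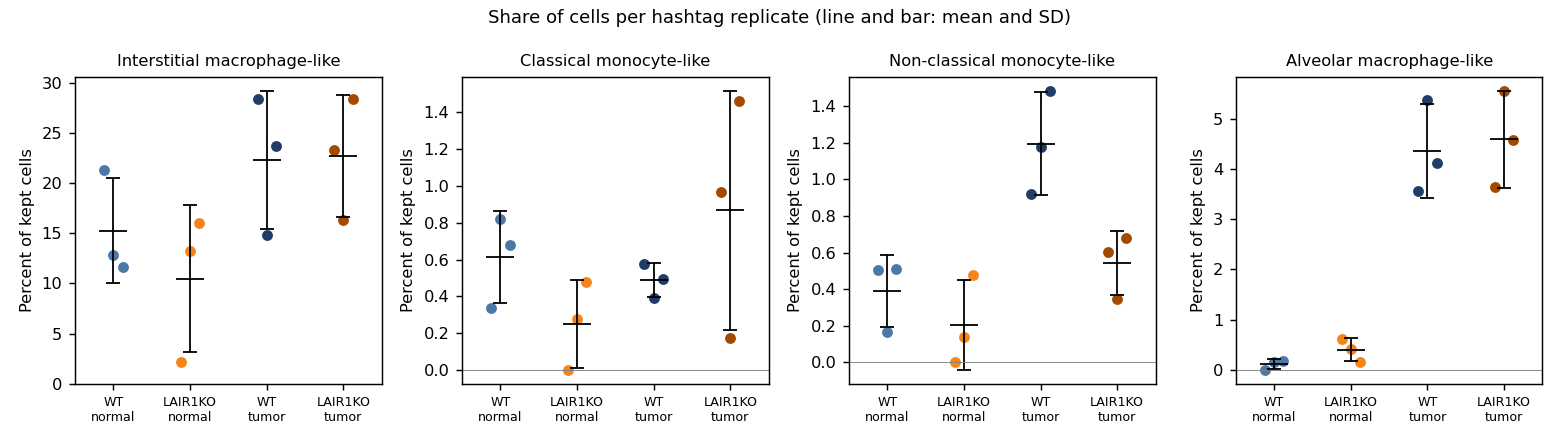
Percent of kept cells in each hashtag replicate (points) with group means and SD for interstitial macrophage-like, classical monocyte-like, non-classical monocyte-like and alveolar macrophage-like cells. Alveolar macrophage-like cells averaged 0.111% and 0.398% in the normal groups and 4.35% and 4.58% in the tumor-bearing groups.

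The genotypes were compared within normal lung to ask what the receptor does without a tumor. In interstitial macrophage-like cells of LAIR1KO normal lung, transcripts best known from neutrophils were higher than in WT. S100a9 and S100a8, the chains of calprotectin, rose from 74.7 ± 19.6 to 480.2 ± 74.3 CPM and from 45.6 ± 3.67 to 347 ± 176 CPM (SD, n = 3). Il1r2, a decoy receptor for interleukin 1, rose by 3.14 ± 0.37 log2 units (adjusted p = 1.98e-04). Retnlg, a secreted protein of granulocytes, had 47 UMIs against 2, a ratio of 34.6 (95% counting interval 9.06 to 294; adjusted p = 0.00705). Runx3, a transcription factor of lymphoid and myeloid cells, rose from 18.2 ± 5.04 to 61.5 ± 19.7 CPM (adjusted p = 0.00445). Of 13 measured genes for chemokine receptors and migration, 2 rose over all genes and 3 when adjusted over the list alone, with none lower. Cxcr4, the receptor for CXCL12, rose by 0.63 ± 0.13 log2 units (adjusted p = 0.0420). Ccr7, which guides cells to lymph nodes, had 40 UMIs against 2 (ratio 29.5, 7.64 to 252; adjusted p = 0.0411).

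Lower in LAIR1KO, besides Lair1, were Sftpc, the surfactant protein C of alveolar type 2 cells, which fell from 357 ± 47.2 to 178 ± 17.1 CPM (adjusted p = 0.00235), and Tcim, a small regulator of transcription (328 ± 43.2 to 133 ± 49.2 CPM, adjusted p = 0.0231). Prkar2b, a regulatory subunit of protein kinase A, was lower too (53.8 ± 15.6 to 20.4 ± 5.77 CPM, adjusted p = 0.0266). Of 16 genes known from LYVE1-high interstitial macrophages, which lie along vessels, 10 fell and 0 rose when adjusted over the list alone, and 0 changed over all genes (median log2 −0.64; camera adjusted p = 1.24e-14). Of 14 genes known from MHCII-high interstitial macrophages, which present antigen, 7 rose and 0 fell when adjusted over the list alone, and 0 over all genes (median log2 0.67; camera adjusted p = 4.91e-11). Both lists lost the call once the correlation among their genes was estimated (adjusted p = 0.150 with an estimated correlation for each). Transcripts of other cells moved with this contrast. The list of neutrophil genes stood at 12.9 UMIs per 10000 in LAIR1KO against 5.80 in WT, and that of endothelial genes at 3.18 against 0.440. Epithelial genes stood at 3.90 against 5.27, and free RNA as the source of Sftpc was not tested.

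By edgeR, 29 genes rose and 12 fell among 7534 tested, 5 of them on chromosomes X or Y, in cells whose largest cluster was 10 in WT (100 of 274 cells) and 6 and 12 in LAIR1KO (56 each of 210). The calls for S100a9, S100a8, Il1r2 and Retnlg ended when doublets called by Scrublet were removed and under another rule for hashtags. For S100a9 the log2 difference was 2.75 ± 0.32 at first, 1.87 ± 0.45 without doublets (adjusted p = 0.0708) and 1.36 ± 0.74 under the other rule (adjusted p = 0.545), so that the estimate shrank and its spread grew. The contrast sets female LAIR1KO against male WT animals. Leaving out the genes on chromosomes X and Y, a check chosen after seeing the data, took the count from 41 to 23. It was 11 without LAIR1KO normal replicate 2 and 69 without LAIR1KO normal replicate 1.

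In tumor-bearing lung, where both genotypes were female, the same comparison asks what the receptor does in the presence of the tumor. Lair1 itself was the single gene that passed the test in interstitial macrophage-like cells among 7534 (0 rose, 1 fell), and 453 genes had an unadjusted p under 0.05. DESeq2 gave the same count, with 215 genes at an unadjusted p under 0.05. In alveolar macrophage-like cells Lair1 fell likewise from 62.8 ± 13.7 CPM to 0 (adjusted p = 0.00538) and was the one call among 4138 genes (268 at an unadjusted p under 0.05), in a test chosen after seeing the data. Cell cycle genes were lower together in LAIR1KO interstitial macrophage-like cells: of 17 measured, 12 fell and 0 rose when adjusted over the list alone, and 0 over all genes (median log2 −1.05; camera adjusted p = 2.14e-12). Genes of LYVE1-high interstitial macrophages leaned up, with 5 of 16 risen and 0 fallen when adjusted over the list alone (median log2 0.43; camera adjusted p = 8.13e-11). Neither list kept its call when its correlation was estimated (adjusted p = 0.259 with an estimated correlation for both). Without LAIR1KO tumor-bearing replicate 3 the cell cycle median was −2.0, and without WT tumor-bearing replicate 3 the LYVE1-high median was 0.29. The list of 5 epithelial genes had 0 risen and 5 fallen members adjusted over the list alone (median log2 −0.75, or −0.42 without WT tumor-bearing replicate 3). Of the 17542 UMIs of that list in WT, 15565 were Scgb1a1 in 1 cell. Without the highest cell of each group the list stood at 6.01 UMIs per 10000 in WT and 5.99 in LAIR1KO. The largest cluster of these cells was 6 in WT (160 of 504) and 9 in LAIR1KO (159 of 579). Cluster 25, a small cluster led by Top2a and Mki67 among others, held 24 of the WT and 14 of the LAIR1KO cells. The cell cycle median was −0.47 at resolution 0.5. A different number of cycling cells was not told apart from a change across the class. The count of genes was 3 when only these groups entered the fit and 143 with no filter on low counts.

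Tumor-bearing was next compared with normal lung in WT mice, to ask what the tumor does to these cells when the receptor is present. In interstitial macrophage-like cells Mpeg1, a pore-forming protein of macrophages, rose from 167 ± 24.6 to 304 ± 34.7 CPM, and F11r, a junctional adhesion molecule, from 24.3 ± 1.95 to 63.2 ± 12.9 CPM (SD, n = 3; adjusted p = 0.0368 for both). AU020206, a long noncoding RNA, rose from 30.6 ± 4.78 to 70.1 ± 6.38 CPM (adjusted p = 0.0368). Prkar2b fell from 53.8 ± 15.6 to 16.3 ± 3.43 CPM (log2 −1.78 ± 0.25, adjusted p = 0.00335). Thbd, the thrombomodulin of vessel walls and some phagocytes, fell from 198 ± 26.9 to 96.2 ± 35.3 CPM, and Fxyd2, a subunit of the sodium pump, from 450 ± 125 to 163 ± 24.1 CPM (adjusted p = 0.0284 for both). Serpinb2, an inhibitor of plasminogen activators that marks macrophages of the body cavities, had 147 UMIs in normal and 0 in tumor-bearing lung, at least 78.1-fold lower (adjusted p = 0.0284).

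Of the 16 genes of LYVE1-high interstitial macrophages, 14 fell and 0 rose when adjusted over the list alone (median log2 −0.65; camera adjusted p = 4.14e-16; adjusted p = 0.159 with an estimated correlation). Of the 14 genes of MHCII-high interstitial macrophages 9 rose and 0 fell by the same count (median log2 0.58; camera adjusted p = 1.81e-11; adjusted p = 0.209 with an estimated correlation). Of 17 cell cycle genes 8 rose and 0 fell (median log2 1.0; camera adjusted p = 4.29e-08; adjusted p = 0.358 with an estimated correlation), with a median of 0.61 without WT tumor-bearing replicate 3. No member of these 3 lists passed over all genes. The cells also lay in other clusters: cluster 10, led by Folr2 among others, held 100 of 274 in normal and 88 of 504 in tumor-bearing lung, and cluster 12, led by H2-Eb1 and H2-Aa among others, 22 and 130. Cluster 25, led by the cell cycle genes Top2a and Mki67 among others, held 9 and 24. The clusters were built from the same counts, so these numbers are not separate support for the lists. Epithelial transcripts stood at 53.8 UMIs per 10000 in tumor-bearing and 5.27 in normal interstitial macrophage-like cells, but 15565 of their 17542 UMIs in tumor-bearing lung were Scgb1a1 in 1 cell, and without it the level was 6.01. By edgeR 7 genes rose and 14 fell among 7534 tested, 6 of them on chromosomes X or Y, since the normal animals were male and the tumor-bearing ones female. Leaving out the genes on those chromosomes, a check chosen after seeing the data, gave 9 calls. DESeq2 called 27 and 24, with Mpeg1 but neither Prkar2b nor Serpinb2. Without WT normal replicate 2 the count fell from 21 to 4.

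The comparison of tumor-bearing with normal lung in LAIR1KO mice asks for the tumor's effect without the receptor, between groups that were both female. In interstitial macrophage-like cells Gdf15, a stress-induced cytokine, rose from 287 ± 106 to 763 ± 175 CPM (SD, n = 3; log2 1.32 ± 0.21, adjusted p = 0.0262). Ifit2, an interferon-induced protein, had 80 UMIs against 1 (ratio 32.1, 95% counting interval 5.60 to 1285; adjusted p = 0.0262), as 1 of 21 measured interferon response genes that rose, both over all genes and when adjusted over the list alone (median log2 0.32, or 0.07 over 10 genes with thinned counts; camera adjusted p = 1.23e-04; adjusted p = 0.225 with an estimated correlation). Among the genes that fell were several known from endothelium, and UMIs of the endothelial list stood at 3.18 per 10000 in normal and 0.408 in tumor-bearing interstitial macrophage-like cells. Adgrf5, Ptprb and Cdh5, surface proteins of endothelium, fell (log2 −3.66, −3.19 and −3.67). So did Ace, the angiotensin-converting enzyme of lung capillaries (−3.57), Fmo1, a monooxygenase (−3.98), and Epas1, a hypoxia-inducible factor (−2.59; adjusted p from 0.0262 to 0.0482 for these genes). Cell cycle genes had 9 of 17 members fallen and 0 risen when adjusted over the list alone (median log2 −1.01; camera adjusted p = 8.44e-07; adjusted p = 0.279 with an estimated correlation). That median was −0.51 without LAIR1KO normal replicate 2 and −2.30 without LAIR1KO tumor-bearing replicate 3. Cluster 25, led by the cell cycle genes Top2a and Mki67 among others, held 8 of 210 cells in normal and 14 of 579 in tumor-bearing lung. Of LYVE1-high genes 2 of 16 rose and 0 fell by the same count (median log2 0.39; camera adjusted p = 7.72e-09; adjusted p = 0.225 with an estimated correlation), with a median of 0.22 without LAIR1KO normal replicate 2. By edgeR 2 genes rose and 10 fell among 7534 tested. The count was 0 without LAIR1KO normal replicate 2, and 0 when cells with 5 or more endothelial UMIs were left out, a check chosen after seeing the data (463 at an unadjusted p under 0.05). There Gdf15 had log2 1.22 ± 0.21 (adjusted p = 0.0554) and Ifit2 7.31 ± 1.12 in place of 4.77 ± 0.77 (adjusted p = 0.0515), a fold over at most 1 UMI in normal lung. Ptprb and Epas1 shrank to −1.85 ± 0.39 and −0.99 ± 0.43, and Adgrf5, Fmo1, Ace and Cdh5 had too few counts to be tested.

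The interaction of genotype and tumor compares the tumor difference of the LAIR1KO libraries with that of the WT libraries, of which WT normal was the only male one. In interstitial macrophage-like cells it passed the test for markers of the LYVE1-high state. Folr2, a folate receptor, stood at 834 ± 71.5 CPM in WT normal, 530.0 ± 27.6 in WT tumor-bearing, 527 ± 171 in LAIR1KO normal and 739 ± 48.4 in LAIR1KO tumor-bearing lung (interaction log2 1.20 ± 0.24, adjusted p = 0.0422). Lyve1, a hyaluronan receptor, stood at 628 ± 172, 271 ± 57.0, 379 ± 194 and 551 ± 137 CPM (1.88 ± 0.38, adjusted p = 0.0495). Cbr2, a carbonyl reductase, stood at 721 ± 46.6, 546 ± 17, 466 ± 53.9 and 759 ± 146 CPM (1.11 ± 0.20, adjusted p = 0.0326). Prkar2b (2.66 ± 0.39, adjusted p = 0.0106), Pepd, a dipeptidase that frees proline from collagen peptides (1.3 ± 0.24, adjusted p = 0.0411), and Tmem267, a membrane protein (3.57 ± 0.69, adjusted p = 0.0422), moved the same way.

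The opposite pattern, higher with the tumor in WT and lower in LAIR1KO, was found for the fractalkine receptor Cx3cr1 at 301 ± 38.4, 443 ± 57.3, 480.5 ± 79.4 and 330.5 ± 5.46 CPM (−1.08 ± 0.21, adjusted p = 0.0412) and for Cxcr4 (−0.89 ± 0.18, adjusted p = 0.0495). It was also found for Mpeg1 (−1.29 ± 0.24, adjusted p = 0.0411), F11r (−2.42 ± 0.37, adjusted p = 0.0107), the integrin Itga6 (−1.66 ± 0.27, adjusted p = 0.0156) and Tspan7, a tetraspanin (−4.87 ± 0.87, adjusted p = 0.0326). UMIs of the endothelial list also rose with the tumor in WT and fell in LAIR1KO (0.440, 0.911, 3.18 and 0.408 per 10000 in the order of the groups above), and Tspan7 is a leading gene of the endothelial cell-like cluster 1. When cells with 5 or more endothelial UMIs were left out, Tspan7 had too few counts to be tested. Folr2, Cbr2, Prkar2b, F11r, Itga6, Mpeg1 and Cx3cr1 passed, while Lyve1, Pepd, Tmem267 and Cxcr4 did not (adjusted p from 0.0502 to 0.0691). The interaction terms of the genes that lost the call changed little in size. They were 1.848 for Lyve1 (from 1.884), 1.185 for Pepd (from 1.296), 3.46 for Tmem267 (from 3.566) and −0.99 for Cxcr4 (from −0.89). Of the 16 LYVE1-high genes 14 rose and 0 fell when adjusted over the list alone, 3 over all genes (median interaction 1.15; camera adjusted p = 1.36e-18; adjusted p = 0.160 with an estimated correlation; fry adjusted p = 0.0412). Of the 14 MHCII-high genes 10 fell and 0 rose, 1 over all genes (median −0.95; camera adjusted p = 5.01e-12; adjusted p = 0.160 with an estimated correlation). Cells of the class changed clusters in the same way: cluster 10, led by Folr2 among others, held 100 of 274, 88 of 504, 36 of 210 and 154 of 579 cells in the order of the groups above. Cluster 25, led by the cell cycle genes Top2a and Mki67 among others, held 9, 24, 8 and 14 of these cells in that order. The clusters were built from the same counts and these numbers are pooled over animals, so they are not separate support for the interaction. Of 17 cell cycle genes 14 fell and 0 rose, 0 over all genes (median −1.99; camera adjusted p = 9.44e-12; adjusted p = 0.170 with an estimated correlation). By edgeR 7 genes rose and 12 fell among 7534 tested. DESeq2 called 69 genes in place of 19. Leaving out WT normal replicate 1 left 2, so that the set of calls depended on single animals.

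**Figure D3:**
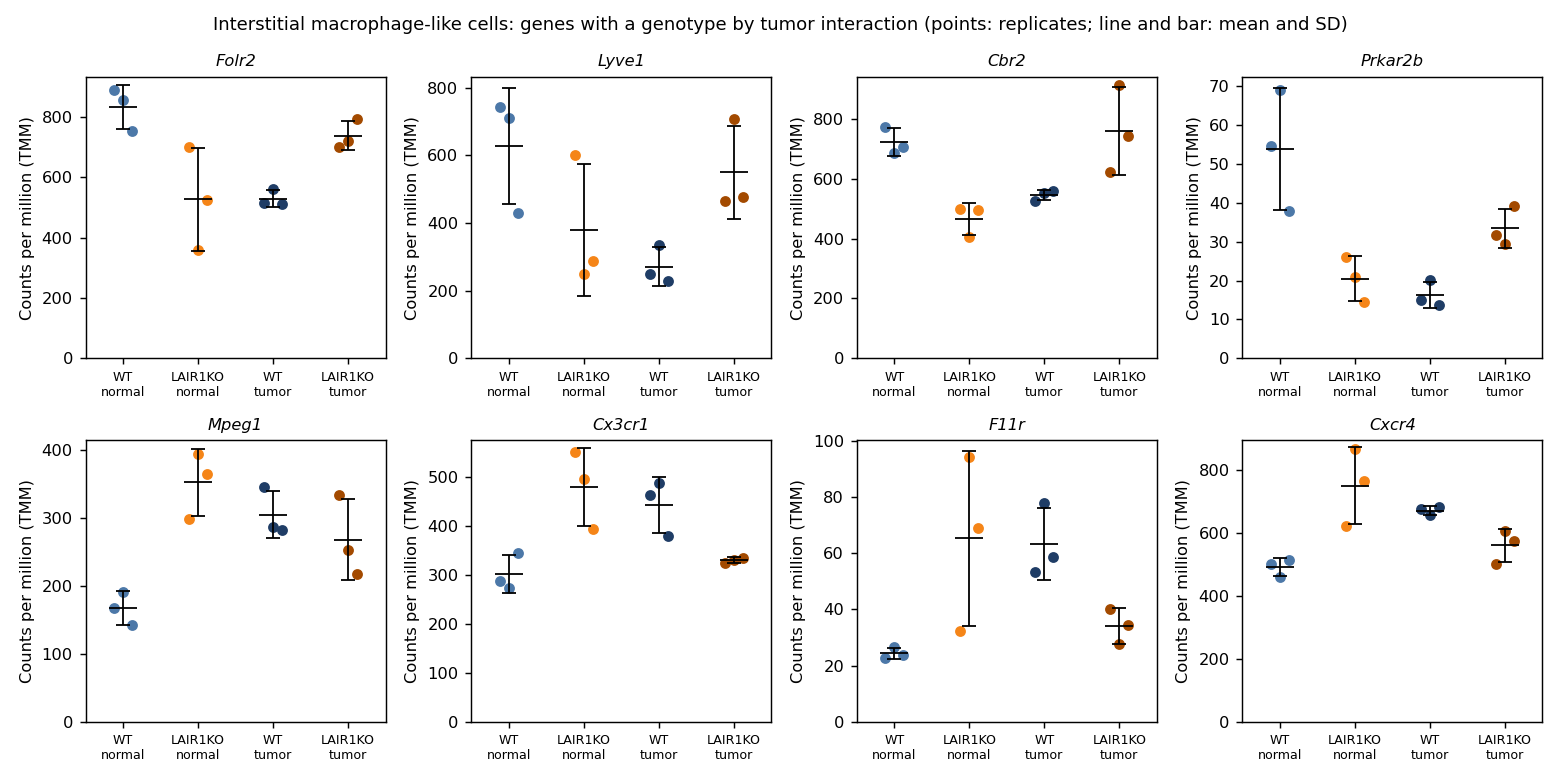
CPM of Folr2, Lyve1, Cbr2, Prkar2b, Mpeg1, Cx3cr1, F11r and Cxcr4 in interstitial macrophage-like cells of each hashtag replicate (points) with group means and SD. Folr2, for example, averaged 834 and 530.0 CPM in WT normal and tumor-bearing lung but 527 and 739 CPM in LAIR1KO.

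**Figure D4:**
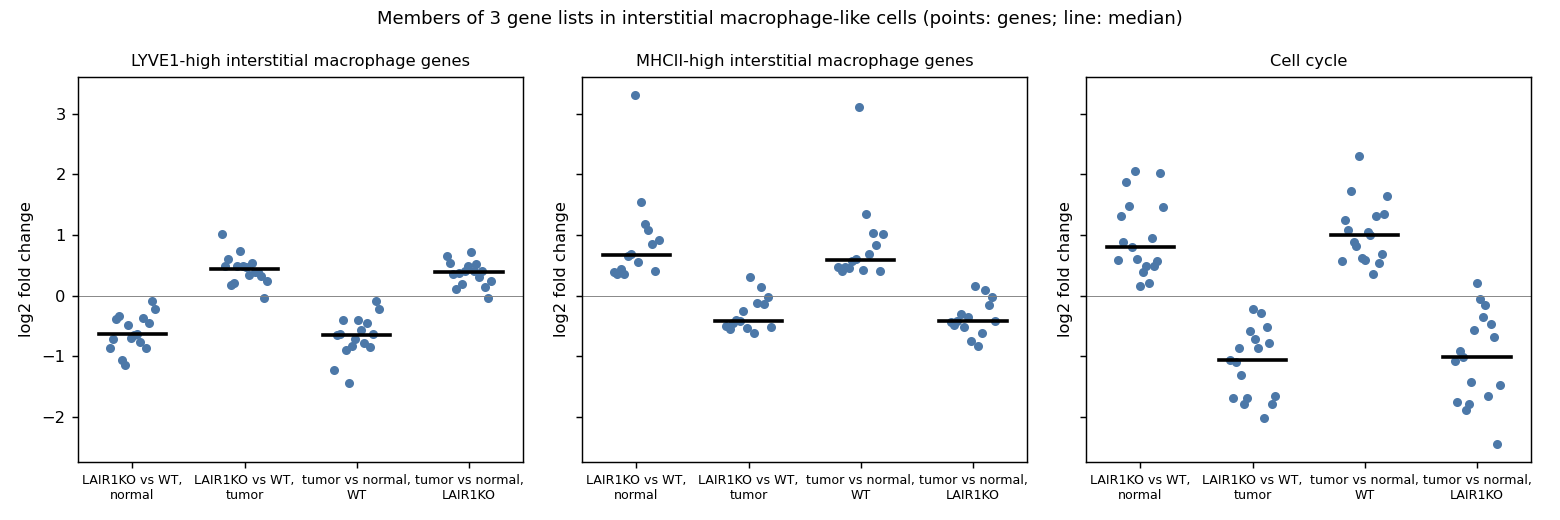
Fitted log2 fold changes of the members (points) of the LYVE1-high, MHCII-high and cell cycle lists in interstitial macrophage-like cells in 4 contrasts, with list medians (lines). The LYVE1-high medians were −0.64 and 0.43 for genotype in normal and tumor-bearing lung, and −0.65 and 0.39 for tumor in WT and LAIR1KO.

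Across 7305 genes of interstitial macrophage-like cells, leaving out Lair1 and chromosomes X and Y, the tumor effect in WT and that in LAIR1KO had a Pearson correlation of −0.116 and a Spearman correlation of −0.152 (jackknife SE over replicates 0.115 for the first). The genotype effects in normal and in tumor-bearing lung had −0.213 and −0.168 (jackknife SE 0.119). These correlations are across genes, which are not independent replicates, and no library was shared between the effects compared.

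Monocytes themselves were too few for the planned gene test, which needed 10 cells per replicate: the 4 groups held 11, 11, 5 and 24 classical and 7, 26, 4 and 14 non-classical monocyte-like cells. Their genes were therefore ranked by size, from summed UMIs with 95% intervals that cover counting error only, with no test between animals. In classical monocyte-like cells of tumor-bearing lung, where 15 of the 24 LAIR1KO cells came from replicate 3, H2-Aa, a chain of MHC class II, had 125 UMIs in LAIR1KO against 2 in WT (log2 ratio 4.97, 3.09 to 8.03). H2-Ab1, its partner chain, had 81 against 0 (at least 13.6-fold higher), and Cd74, the invariant chain, 381 against 29 (2.72, 2.18 to 3.32). Il1b, the inflammatory cytokine interleukin 1 beta, was higher there too, by 1.51 (1.10 to 1.94). In normal lung Cd74 was likewise higher in LAIR1KO (67 against 41 UMIs; 2.12, 1.54 to 2.72). Cxcr4 was higher as well (1.79). With the tumor, Nfkbia, the inhibitor of NF-kB, was higher in classical monocyte-like cells of WT (56 against 18 UMIs; 1.90, 1.11 to 2.75) and of LAIR1KO (103 against 1; 4.54, 2.03 to 9.86). Ccl2, the ligand that draws monocytes, was higher in LAIR1KO (65 against 1; 3.88).

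In non-classical monocyte-like cells Il1b was lower in LAIR1KO than in WT, with 9 against 133 UMIs in normal lung (−2.49, −3.65 to −1.52) and 75 against 239 in tumor-bearing lung (−1.29, −1.68 to −0.91). Ifi27l2a, an interferon-induced gene, was higher with the tumor in WT (105 against 7 UMIs; 2.50, 1.40 to 3.84). The surfactant transcript Sftpc was higher in LAIR1KO than in WT tumor-bearing cells (318 against 35 UMIs; 3.57, 3.06 to 4.11), beside Gsn (2.79) and Mgp (1.44), which are known from stroma. The leading genes of the non-classical sub-cluster itself included Bgn, Inmt and Npnt, which also lead the fibroblast-like cluster 2. What such transcripts did to the ratios of this class was not tested. An edgeR test without the minimum of cells, chosen after seeing the data, called Xist alone, in classical cells for tumor in WT and in non-classical cells for genotype in normal lung and for tumor in WT. The cluster that held both kinds of monocytes could be tested with 2 replicates against 2 in normal lung, where Cxcl3, a neutrophil-attracting chemokine, rose from 27.2 ± 19.1 to 666 ± 246 CPM in LAIR1KO (adjusted p = 0.00239). Cells led by neutrophil markers made up 12 of its 34 cells in WT normal and 13 of 24 in LAIR1KO normal lung, so that this rise is not a result on monocytes alone. In tumor-bearing lung 0 genes passed between genotypes in that cluster by edgeR (81 at an unadjusted p under 0.05) and 0 by DESeq2, and the same held for tumor in LAIR1KO (0 by both, 104 unadjusted).

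In neutrophil-like cells a second receptor gene near Lair1 differed between genotypes. Pira2, an activating receptor of the paired immunoglobulin-like family (mm10, chromosome 7, 3836812 to 3845051), rose in LAIR1KO from 212 ± 23.9 to 757 ± 109 CPM in normal lung (log2 1.80 ± 0.16, adjusted p = 1.78e-08) and from 199 ± 34.2 to 709 ± 95.4 CPM in tumor-bearing lung (1.86 ± 0.17, adjusted p = 6.56e-08; SD, n = 3). Both calls held under each alternative tried, but the family has near-identical members, so the identity of the gene is uncertain. In normal lung interferon response genes were higher in LAIR1KO neutrophil-like cells, of which 17 of 536 lay in cluster 26, led by Slfn4 and Rsad2 among others, against 6 of 577 in WT. Of these, 5 of 16 rose and 0 fell over all genes, and 12 rose when adjusted over the list alone (median log2 1.0; camera adjusted p = 1.53e-15; adjusted p = 0.0597 with an estimated correlation), Slfn5 among them (47.1 ± 6.52 to 151 ± 46.7 CPM, adjusted p = 5.08e-05). WT normal was the male library, so sex and genotype cannot be told apart for these interferon response genes. Sftpc fell in LAIR1KO neutrophil-like cells by 1.11 and 0.75 log2 units in normal and tumor-bearing lung (adjusted p = 1.56e-05 and 0.0108), and Sftpa1, another surfactant protein, in normal lung (log2 −1.36, adjusted p = 0.00483). In tumor-bearing lung Scgb1a1, the secreted protein of airway club cells, was higher in LAIR1KO (log2 0.82, adjusted p = 0.00491) and Lair1 lower (adjusted p = 0.0206). UMIs of the epithelial list were found in 61.2 to 81.3% of the neutrophil-like cells of a library. Free RNA as the source of these epithelial transcripts was not tested.

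With the tumor, Scgb1a1 rose in neutrophil-like cells of both genotypes, from 103 ± 4.53 to 341 ± 51.0 CPM in WT (adjusted p = 2.23e-07). In LAIR1KO it rose from 218 ± 27.6 to 597 ± 53.6 CPM (adjusted p = 7.31e-07). In WT, interferon response genes rose as well, 4 of 16 over all genes and 9 when adjusted over the list alone, with 0 fallen (median log2 0.70; camera adjusted p = 8.61e-09; adjusted p = 0.112 with an estimated correlation), with a median of 0.44 without WT tumor-bearing replicate 3. Ifi27l2a rose there from 500.4 ± 44.9 to 1317 ± 390 CPM (adjusted p = 1.64e-05). The normal side of these interferon differences was the male WT library, as for genotype in normal lung. The histone gene Hist1h2bc and Atp5md, of the mitochondrial ATP synthase, fell (log2 −0.83 and −0.71, adjusted p = 0.0111 and 0.0112). Ribosomal protein genes fell, 16 of 77 over all genes and 40 when adjusted over the list alone (median log2 −0.40; camera adjusted p = 1.67e-28; adjusted p = 0.0715 with an estimated correlation). In LAIR1KO Il1rn, the interleukin 1 receptor antagonist, rose by 0.67 ± 0.13 log2 units (adjusted p = 0.0259), and Tsc22d3, a glucocorticoid-induced gene, fell by 1.54 ± 0.26 (adjusted p = 0.00637), as did the kinase Stk17b (log2 −0.61, adjusted p = 0.0275). Among 3327 genes, edgeR called 14 risen and 12 fallen for genotype in normal lung, 5 and 6 in tumor-bearing lung, 44 and 37 for tumor in WT and 6 and 3 in LAIR1KO. DESeq2 called 11 and 5, 8 and 3, 32 and 22, and 8 and 6.

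Alveolar type 2 epithelium-like cells differed mainly where LAIR1KO normal lung was one side, and most such cells of that library lay in a cluster that was minor in the other groups. Cluster 17, with Scrublet calls in 20.2% of its cells, held 56 of the 101 such cells of LAIR1KO normal lung, against 23 of 190 in WT normal, 27 of 193 in WT tumor-bearing and 13 of 122 in LAIR1KO tumor-bearing lung. Sftpc, their most typical product, fell in LAIR1KO normal lung by 0.59 log2 units (adjusted p = 9.17e-07), and Cdo1, an enzyme of cysteine breakdown, rose by 3.58 ± 0.31 (12.1 ± 6.70 to 147 ± 48.7 CPM, adjusted p = 3.82e-06). Both calls held under each alternative. Sftpb, another surfactant protein, fell there (log2 −0.65) and Marcks, a substrate of protein kinase C, rose (2.24; adjusted p = 1.31e-05 for both). Calcrl, an endothelial receptor, was the one call between genotypes in tumor-bearing lung (log2 −1.78, adjusted p = 0.0196), and it reversed to 0.13 without cluster 17 and to 0.14 under another rule for hashtags. In WT, Ccl4 and Ccl3, chemokines of inflamed tissue, rose with the tumor by 4.73 ± 0.75 and 2.88 ± 0.51 log2 units (adjusted p = 0.00664 and 0.0176), calls that DESeq2 did not make. Both are among the leading genes of the interstitial macrophage-like cluster 9, and macrophage transcripts as their source here were not tested. Errfi1, a feedback inhibitor of EGFR, fell in WT (log2 −0.60, adjusted p = 0.00907). In LAIR1KO the keratin Krt18 and Cbr2 rose with the tumor (log2 1.14 and 0.64, adjusted p = 1.09e-04 and 1.93e-04), and Calcrl and Cavin2, both known from endothelium, fell (−3.79 and −2.99, adjusted p = 3.90e-08 and 5.75e-06). The genes called were 534 risen and 257 fallen for genotype in normal lung, 0 and 1 in tumor-bearing lung, 5 and 9 for tumor in WT and 175 and 395 in LAIR1KO. DESeq2 gave 373 and 105 for genotype in normal lung and 81 and 295 for tumor in LAIR1KO. Of 7 endothelial genes in these cells 6 rose over all genes in LAIR1KO normal lung (median log2 1.59; camera adjusted p = 1.11e-09; adjusted p = 0.0759 with an estimated correlation) and all 7 fell with the tumor in LAIR1KO (median log2 −3.11; camera adjusted p = 7.49e-14; adjusted p = 0.0808 with an estimated correlation). Without cluster 17, a check chosen after seeing the data, the counts were 42 and 10 for genotype in normal lung and 2 and 41 for tumor in LAIR1KO. The medians of the 3 endothelial genes still measured were then 0.86 and −0.71.

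In endothelial cell-like cells Scgb1a1 rose with the tumor in WT, from 36 ± 11.4 to 226 ± 33 CPM (adjusted p = 3.65e-06), and in LAIR1KO by 1.63 ± 0.18 log2 units (adjusted p = 1.93e-04). Ccl6, a chemokine of myeloid cells, rose there too (log2 2.50, adjusted p = 0.00662). Gsn, an actin-severing protein, and Inmt, a methyltransferase, fell with the tumor in LAIR1KO (log2 −2.27 and −1.98, adjusted p = 8.04e-04 and 9.24e-04). Both are known from stroma, and Inmt is a leading gene of the fibroblast-like cluster 2 and of the unnamed cluster 8, which made up 16.5% of LAIR1KO normal and 0.658% of LAIR1KO tumor-bearing cells. In LAIR1KO normal lung Fhl1, a LIM domain protein, and Gyg, the primer of glycogen, rose (log2 1.43 and 1.59, adjusted p = 0.00222 for both) and Sftpc fell (−1.10, adjusted p = 0.00893). Scgb1a1 and Sftpc are transcripts of epithelium, and free RNA as their source in these cells was not tested. In fibroblast-like cells of LAIR1KO normal lung Adgrf5 and Tspan7, both known from endothelium, rose (log2 3.22 and 2.57, adjusted p = 0.00848 and 0.0153), and H3f3b, a histone gene, fell (−0.69, adjusted p = 0.00597). Scgb1a1 rose with the tumor in WT fibroblast-like cells (log2 1.5, adjusted p = 1.03e-04), and Idi1, an enzyme of isoprenoid synthesis, rose with the tumor in both genotypes, by 1.0 ± 0.17 log2 units in WT and 1.39 ± 0.23 in LAIR1KO (adjusted p = 0.0111 and 0.0323). Apoe, the lipid carrier, and Itgbl1, an integrin-like protein, fell in WT (log2 −0.67 ± 0.12 and −1.10, adjusted p = 0.0136 and 0.0163). Ctla2a and Epas1, both high in endothelium, fell in LAIR1KO (log2 −3.04 and −1.82, adjusted p = 0.00366 and 0.0415). Between genotypes in tumor-bearing lung 0 genes passed by edgeR in endothelial cell-like cells (311 at an unadjusted p under 0.05) or in fibroblast-like cells (393), and 0 by DESeq2 in either class. In normal lung edgeR called 36 risen and 4 fallen in endothelial cell-like and 8 and 4 in fibroblast-like cells. With the tumor it called 2 and 2 and 7 and 8 in WT, and 14 and 65 and 1 and 6 in LAIR1KO. DESeq2 called 7 and 19 for tumor in WT fibroblast-like cells.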

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

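Of the tests in this part, those of the endothelial transcripts other than their spread over cells, of hashtag loss of alveolar macrophages, of the tumor as their source and of sex were chosen only after the result was seen.

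Genes whose tumor difference was not alike in the WT and LAIR1KO libraries in interstitial macrophage-like cells drew attention first. Their interaction terms in log2 units were 2.66 for Prkar2b, 1.11 for Cbr2, 1.3 for Pepd, 3.57 for Tmem267, 1.20 for Folr2 and 1.88 for Lyve1, and −2.42 for F11r, −1.66 for Itga6, −4.87 for Tspan7, −1.29 for Mpeg1, −1.08 for Cx3cr1 and −0.89 for Cxcr4. Only 1 of 100 groupings of the replicates, the real one, called as many as 19 genes in the interaction, with 16 in the highest other. Random regrouping of the animals thus did not reach that count in these draws, though it came as near as 16. It mixes replicates of libraries that differ in sex, genotype and tumor, so it cannot tell an interaction from other differences between the libraries.

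In the LYVE1-high list, WT normal and LAIR1KO tumor-bearing lung stood on one side and the other groups on the other, while WT normal was the only male group. With counts thinned to the smallest replicate, the list median for tumor in WT stayed at −0.65. The other medians kept their sign but shrank when thinned. They went from −0.64 to −0.44 (genotype in normal lung), 0.43 to 0.36 (genotype in tumor-bearing lung) and 0.39 to 0.25 (tumor in LAIR1KO). Thinning evens out the summed totals, which the test already scales for. It cannot show what depth per cell did to the calling and naming of cells. Depth thus stays open for all of these medians. Sex is argued against for the differences among the female groups, since the same list had a median of 0.43 between the tumor-bearing groups. For the differences from WT normal, as in the median of −0.65, sex may be the source. WT normal differs from the others in sex and library at once, so there sex cannot be told apart from the biological explanation, that LAIR1 and the tumor act on the same macrophage states.

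Interstitial macrophage-like cells of LAIR1KO normal lung carried 442 UMIs of the endothelial list in 210 cells, of which 5 cells held 340. Free RNA is argued against for most of them, because 76.9% of the UMIs lay in cells with 5 or more, where it would have spread over all cells, but for the rest it stays open, since the other cells held 1.87 times as many per 10000 as in any other group (0.783 against 0.419 or less). Droplets that held an endothelial cell as well stay open. The 5 cells with 5 or more of these UMIs had a median of 16500 UMIs in all, against 5290 in the others. A cutoff on UMIs also favors cells with many UMIs, so this cannot decide. Picked instead by their share, 5 or more per 10000, the cells had 1.07 times the median total UMIs of the others. Among macrophage-type cells the share of hashtag doublets was 3.00 times as high in those picked by this share as in the others (4 of 27 against 26 of 526), as droplets of cells from different mice would give. A biological explanation, an endothelial program in macrophages, was not tested apart from these values.

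Alveolar macrophage-like cells were scarce in both normal libraries, although they are common in healthy lungs. Loss in the assignment of hashtags is argued against, since among all filtered cells their share in the normal libraries was still 0.0802 times that in the tumor-bearing ones. Loss in the cell filters is argued against too, since 0 barcodes of the normal libraries outside the filters carried 3 or more of their markers and more of these than of interstitial macrophage markers (195 and 70 barcodes were outside). The tumor in the lung stays open: the lowest share of a tumor-bearing library was 7.59 times the highest of a normal one, yet tissue collection or dissociation by library could give the same, and the 2 cannot be told apart in a design with a single library per group.

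Cluster 8, which was led by endothelial and fibroblast genes and stayed unnamed, made up 16.5% of kept cells in LAIR1KO normal lung, against 1.78% in WT normal, 0.759% in WT tumor-bearing and 0.658% in LAIR1KO tumor-bearing lung. Tyrp1, a melanocyte enzyme outside the comparisons, had 18 UMIs in the WT and 572 in the LAIR1KO tumor-bearing library, and 0 in both normal libraries.

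The counts of changed genes between 3 and 3 replicates allow 10 splits, too few for a share under 0.05. For genotype in normal lung the real count was 41 in interstitial macrophage-like cells (highest other split 9; 1 split as large) and 871 over the other classes (5; 1), and in tumor-bearing lung 1 (1; 2 splits) and 12 (6; 1). For tumor in WT it was 21 (1; 1) and 115 (2; 1), and in LAIR1KO 12 (0; 1) and 665 (27; 1). For genotype in tumor-bearing alveolar macrophage-like cells it was 1 (2; 5 splits).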

How the results depend on the processing

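Alternatives chosen only after the result was seen were the rescue of cells without a hashtag call, cluster 17 left out, genes on chromosomes X and Y left out, macrophages with endothelial transcripts left out, and the monocyte and alveolar macrophage tests. No paired analysis was possible because the labels give no replicate numbers that pair animals across groups. Of 87 named gene results past the threshold 14 stayed so under every alternative in which the gene was tested, in interstitial macrophage-like cells 2 of 39 (Lair1 for genotype in normal and in tumor-bearing lung). Over all named genes and the alternatives that tested them, 1999 values kept their side of the threshold, and their direction where the gene was called at first. Another 421 lost the call (a gene that DESeq2 gave no adjusted p counts as lost) and 11 gained one. Among genes called at first, 2 values reversed. These were Calcrl in alveolar type 2 epithelium-like cells for genotype in tumor-bearing lung, to 0.14 under the hashtag margin rule and 0.13 without cluster 17; the cause was not tested. Of the counts of genes 134 stayed within 1.5 times and 90 moved. Of the shares 405 kept direction and side, 11 lost and 8 gained the call and 8 reversed. Lost were fibroblast-like cells with TMM factors (both contrasts), without WT normal 3 (genotype in normal lung) and without LAIR1KO tumor-bearing 3 (tumor in LAIR1KO), pericyte or smooth muscle-like cells without 3 single replicates, T cell-like cells with TMM factors and without 2 single replicates, and alveolar macrophage-like cells for tumor in LAIR1KO with mononuclear phagocytes as the denominator (2.10, adjusted p = 0.0566). With no low-count filter more genes were tested, and with thinned or fewer replicates less depth or fewer samples entered. The cause of the other shifts was not tested.

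Counts of genes in interstitial macrophage-like cells moved as follows. With no low-count filter they became 299 (from 41, genotype in normal lung), 143 (from 1, genotype in tumor-bearing lung), 267 (from 21, tumor in WT), 204 (from 12, tumor in LAIR1KO) and 380 (from 19, interaction). With thinned counts they were 16, 2, 4, 3 and 4 in that order. With only the 2 groups compared they were 22 and 3 for genotype and 7 for tumor in LAIR1KO. DESeq2 gave 51 for tumor in WT and 69 for the interaction. The hashtag margin rule gave 75 for genotype in normal lung, 44 for tumor in LAIR1KO and 59 for the interaction, and removal of Scrublet doublets 29 for the interaction. Resolution 0.5 gave 42 for tumor in WT, 0 in LAIR1KO and 53 for the interaction, and resolution 2.0 gave 43 for the interaction. Rescued cells gave 68, 60, 2 and 72 for genotype in normal lung, tumor in WT, tumor in LAIR1KO and the interaction. Without X and Y the counts were 23 for genotype in normal lung and 9 for tumor in WT, and without endothelial transcripts 2, 0 and 11 for genotype in tumor-bearing lung, tumor in LAIR1KO and the interaction. Leaving out a replicate gave 11 (without LAIR1KO normal 2) to 69 (LAIR1KO normal 1) for genotype in normal lung and 1 to 3 (WT tumor-bearing 2) in tumor-bearing lung. It gave 4 (WT normal 2) to 45 (LAIR1KO normal 1) for tumor in WT, 0 (LAIR1KO normal 2) to 18 (LAIR1KO normal 3) in LAIR1KO and 2 (WT normal 1) to 98 (LAIR1KO normal 1) for the interaction.

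Over the other classes the count for genotype in normal lung, 871, became 568 with DESeq2, 1581 with no filter, 255 thinned, 125 with the strict cell filter, 436 under the margin rule, 132 without cluster 17, and 530 (without LAIR1KO normal 2) to 984 (LAIR1KO tumor-bearing 1) with a replicate left out. In tumor-bearing lung 12 became 278 with no filter, 4 thinned, 21 without Scrublet doublets and 3 (WT tumor-bearing 2) to 25 (LAIR1KO tumor-bearing 3). For tumor in WT 115 became 424 with no filter, 26 thinned, 177 with the 2 groups alone and 48 (WT normal 1) to 132 (LAIR1KO normal 1). For tumor in LAIR1KO 665 became 1358 with no filter, 254 thinned, 370 with the 2 groups alone, 172 with the strict filter, 138 without cluster 17 and 271 (LAIR1KO tumor-bearing 3) to 790 (LAIR1KO normal 1).

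Shares (log2) reversed for interstitial macrophage-like cells for genotype in normal lung with rescued cells (0.17), for genotype in tumor-bearing lung with TMM factors (−0.045), rescued cells (−0.0924) and single replicates left out (−0.20 without WT tumor-bearing 2 to 0.24 without WT tumor-bearing 1; −0.17 without LAIR1KO tumor-bearing 3). They also reversed for tumor with mononuclear phagocytes as the denominator (−0.26 in WT, −0.19 in LAIR1KO). Classical monocyte-like cells for tumor in WT reversed with rescued cells (0.0017), and in LAIR1KO passed the threshold with the strict filter (2.07, adjusted p = 0.0411) and the margin rule (2.03, adjusted p = 0.0386). Left-out replicates moved tumor in LAIR1KO between 1.23 (without LAIR1KO tumor-bearing 3) and 2.53 (LAIR1KO normal 3) for classical monocyte-like, 0.64 (LAIR1KO normal 1) and 1.56 (LAIR1KO normal 3) for interstitial macrophage-like and 0.89 (LAIR1KO normal 1) and 2.69 (LAIR1KO normal 3) for non-classical monocyte-like cells. The 3 values without LAIR1KO normal 3 passed the threshold (adjusted p = 0.0359, 0.0359 and 0.0390), as did classical monocyte-like cells without LAIR1KO tumor-bearing 2 (2.21) and interstitial macrophage-like cells without LAIR1KO normal 2 or tumor-bearing 2 (1.32 and 1.3). With rescued cells tumor in LAIR1KO gave 0.99 for classical monocyte-like and 0.33 for interstitial macrophage-like cells. Of the interstitial macrophage list calls 0 were made with an estimated correlation and 2 by fry. The correlation of tumor effects became 0.0341 thinned, and that of genotype effects −0.065 with no filter, −0.0903 thinned and −0.071 at resolution 0.5. The cell cycle medians became −0.47 (from −1.05, genotype in tumor-bearing lung) and −0.32 (from −1.01, tumor in LAIR1KO) at resolution 0.5, and the second −0.47 without endothelial transcripts, −0.56 under the margin rule and −0.64 with rescued cells. The interaction median of that list became −0.99 at resolution 0.5 and −1.28 without endothelial transcripts. Interferon medians of neutrophil-like cells became 0.61 thinned (genotype in normal lung) and 0.36 with no filter (tumor in WT). Few cells limit what can be said of monocytes, and so does hashtag loss for LAIR1KO normal interstitial macrophage-like cells, of which 56.6% had no hashtag call.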

Other observations

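Values chosen only after the result was seen in this part are those of the melanoma genes, of Scgb1a1 and Sftpc across classes, and of the genes near Lair1.

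Melanoma transcripts differed between the tumor-bearing libraries. The LAIR1KO library held 590 UMIs of Pmel and 1317 of Dct, pigment genes of melanocytes, against 33 and 32 in the WT library, and 246 against 38 of Mlana. Cells were counted that held UMIs of 3 or more of Pmel, Dct, Mlana, Tyrp1, Tyr and Ptgds, the melanoma list. They numbered 5 in LAIR1KO (3 of them among interstitial macrophage-like cells, 1 pericyte or smooth muscle-like and 1 unnamed) and 1 in WT (unnamed), and 0 in the normal libraries. In LAIR1KO normal lung the share of pericyte or smooth muscle-like cells rose to 1.99% ± 1.06 (SD, n = 3) from 0.392% ± 0.257 in WT (log2 2.29, adjusted p = 0.0103, edgeR), a call that ended without WT normal replicate 2 or 3 or LAIR1KO normal replicate 1 (adjusted p = 0.0892, 0.0644 and 0.0560). In LAIR1KO the tumor came with more T cell-like cells, 1.95% against 0.483% in normal lung (log2 1.96, adjusted p = 0.0183). This was 1.38 (adjusted p = 0.0243) once cells without a hashtag call were rescued, 1.41 without LAIR1KO normal replicate 1 and 1.78 without LAIR1KO tumor-bearing replicate 1 (adjusted p = 0.0570 and 0.0518). There were fewer alveolar type 1 epithelium-like cells, 0.623% against 2.88% (log2 −2.30, adjusted p = 0.00241).

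Some transcripts moved alike in unrelated cell types. Scgb1a1 rose with the tumor in neutrophil-like, endothelial cell-like and fibroblast-like cells of WT (log2 1.71, 2.58 and 1.5; adjusted p = 2.23e-07, 3.65e-06 and 1.03e-04). Sftpc fell in LAIR1KO normal lung in interstitial macrophage-like, neutrophil-like, endothelial cell-like and alveolar type 2 epithelium-like cells (log2 −1.03, −1.11, −1.10 and −0.59). Both are transcripts of epithelium, and 61.2 to 81.3% of the neutrophil-like cells of a library held 1 or more UMIs of the epithelial list. Free RNA as their source was not tested, so outside epithelium these shifts need not be changes of expression. In alveolar type 2 epithelium-like cells of tumor-bearing lung, ribosomal protein genes were higher in LAIR1KO, with 57 of 77 risen and 0 fallen when adjusted over the list alone and 0 over all genes (median log2 0.28; camera adjusted p = 7.22e-62; adjusted p = 0.0214 with an estimated correlation; fry adjusted p = 0.00103). Of the genes near Lair1 on proximal chromosome 7, 1 of 10 measured rose in LAIR1KO neutrophil-like cells in normal and in tumor-bearing lung (Pira2), with list medians of 0.03 and 0.08; in interstitial macrophage-like cells 0 of 18 passed the test in either.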
